A study of Mus musculus with 14 samples.

How the data were processed

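Polyadenylated RNA was measured by sequencing in 14 libraries of CD8 T cells isolated from mice and grown in culture. The cells were activated with antibodies against CD3 and CD28 on day 0 and expanded for 8 days. The KO and WT groups, with 3 libraries each, carried a tamoxifen-inducible Cre (CreERT2) with Dot1l alleles that were floxed or wild type, and both received 10 nM 4-hydroxytamoxifen on day 0. The DMSO and EPZ groups, with 4 libraries each, came from mice without Cre or floxed alleles, and received 0.1% DMSO or the DOT1L inhibitor EPZ-5676 every other day. The labels give the inhibitor dose as 10 mM in the treatment field and as 10 uM in the library name, and the files do not settle which holds. The libraries were stranded and prepared from RNA that had passed a filter on RNA integrity.

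The authors deposited raw read counts per Ensembl gene, 1 column per library, with no normalization. Per the labels, TopHat2 2.1 and Bowtie 1.1 were used with the mm10 genome build, and HTSeq is named as well. The strand setting of the counting and the release of the gene annotation are not given in the sources used here. The table holds 55486 genes, and 54906 of them (99.0%) have the same coordinates as in GENCODE mouse release 21. A further line without a gene name held 0 counts and was left out. All 14 columns were assigned to a library. Library totals ran from 5643724 to 20586093 counts, a ratio of 3.65. Where a group of libraries held no count of a gene, the floor was 3 counts over the summed total of the group. Intervals of count ratios and floors rest on counts pooled over the libraries of a group. They cover counting error only and leave out the spread between replicates. The reads carry no molecular identifiers, so even the counting error may be understated. No pair of replicates was a copy of another, with a chi-square per degree of freedom of 2.05 to 18.1 over genes with at least 20 counts in the pair.

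Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter (a minimum count of 10 and a minimum total of 15) and the quasi-likelihood F-test. The Benjamini-Hochberg adjusted p was called at 0.05 over all genes tested. KO was compared with WT and EPZ with DMSO, each within its own experiment, and the contrast of the effects, (KO minus WT) minus (EPZ minus DMSO), was fitted on all 14 libraries. Standard errors were derived from the fold change and its F statistic. Levels are in CPM, the counts scaled to a common library total with the TMM factors, as mean ± SD. The library names give the same animals, WT1 to WT4, in the DMSO and EPZ groups. After the group means were removed, 3 of the 4 pairs had a correlation above 0.1 (range 0.0324 to 0.554) and 3 of 4 libraries were closest to the other library of their own animal, so a fit with the animal as a block was run as an alternative. Shared calls were counted among genes tested in both comparisons and set against the product of the shares called. Correlations of fold changes run across genes, which are not independent replicates. Measures of library quality were compared with exact two-sided permutation tests, adjusted over 6 tests. These permuted all libraries of a comparison freely and did not use the pairing of DMSO and EPZ libraries by animal.

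A total of 26 gene lists was fixed: cytotoxic effector molecules, effector cytokines and chemokines, type 2 and type 17 cytokine genes, NK receptors and adaptors, naive and memory T cell genes, effector transcription factors, inhibitory receptors and exhaustion genes, T cell receptor signalling, cytokine and costimulatory receptors, chemokine receptors and adhesion, DOT1L and its partners, MLL leukaemia DOT1L targets, Polycomb and chromatin repressors, cholesterol synthesis and uptake, glycolysis, oxidative phosphorylation, interferon response, cell cycle, p53 targets and apoptosis, integrated stress response, heat shock and immediate early genes, and markers of B cells, of myeloid and dendritic cells, of CD4 and regulatory T cells, of gamma delta and innate-like T cells, and of erythroid cells and platelets. Lists with at least 3 members tested were compared with all other genes by camera in limma 3.58.1, with a preset correlation of 0.01 between genes, and again with an estimated correlation. The adjusted p of a list is over the lists. Members were counted by their adjusted p over all genes and adjusted over the list alone.

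The named genes include Dot1l, Gzmb, Prf1, Ifng, Tbx21, Eomes, Tcf7 and Pdcd1. To these were added the 8 genes higher and the 8 lower with the largest change among those called, with at least 5 CPM in the higher group, no overlap between the groups, and no predicted gene or receptor segment. From each list called, up to 4 members with the smallest adjusted p were named, and from each other list up to 2. The 8 genes called in both comparisons with the largest smaller change, and the 5 genes per side with the largest difference of effects, complete the rule. The groups, tests, lists, this rule and the alternatives were chosen before the data were examined, except where the text says that a gene or a test was chosen afterwards.

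The alternatives were size factors from DESeq2 (RLE), no filter, a filter of 10 CPM, the DESeq2 1.42.0 Wald test, limma voom, the replicate number as a block, the labelled sex as a covariate, all libraries in 1 fit, glmTreat with a minimum fold of 1.5, fry and an estimated correlation for the lists, and each library left out in turn. A covariate for the sex read from Xist and Ddx3y, and counts thinned at random to the smallest library (seed 1), were added after seeing the data, as was the animal as a block in the test of the EPZ effect by sex. The tests were tried on simulated data drawn from the mean levels of these libraries, with a common spread for all genes and 200 genes changed. At 2-fold, 66 of 67 changed genes were recovered for KO against WT, 64 of 67 for EPZ against DMSO, and 53 of 65 for the contrast of the effects. False calls numbered 8 of 191, 6 of 188 and 10 of 161. Far more genes were called in the real data and their spread differs by gene, so these are not error rates of the calls reported here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.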

Results

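The transcriptomes of cultured mouse CD8 T cells were counted after 8 days, in cells labelled as having lost the histone H3 lysine 79 methyltransferase DOT1L (KO, 3 libraries) with Dot1l wild-type controls (WT, 3 libraries), and in wild-type cells given the DOT1L inhibitor EPZ-5676 (EPZ, 4 libraries) or its solvent (DMSO, 4 libraries). The totals of the KO libraries were 7879305, 18831278 and 8968961 counts, and those of the WT libraries 8702784, 5643724 and 20095758. The DMSO libraries held 20586093, 12293746, 8139437 and 11589004 counts, and the EPZ libraries 17609169, 17914906, 18927634 and 11927364. Mitochondrial genes took 1.61% ± 0.184 (SD, n = 3) of counts in KO and 1.21% ± 0.184 (SD, n = 3) in WT, a difference with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow (adjusted p = 0.514). In EPZ the share was 0.869% ± 0.150 and in DMSO 1.02% ± 0.327 (SD, n = 4 each; exact two-sided permutation p = 0.429, adjusted p = 0.643). The first principal component of 12639 genes held 55.7% of the variance and the second 17.1%. On the first, the KO libraries lay from 69.7 to 74.7, WT from -5.22 to 7.92, EPZ from -18.2 to -2.86 and DMSO from -48.4 to -40.9.

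**Figure D1:**
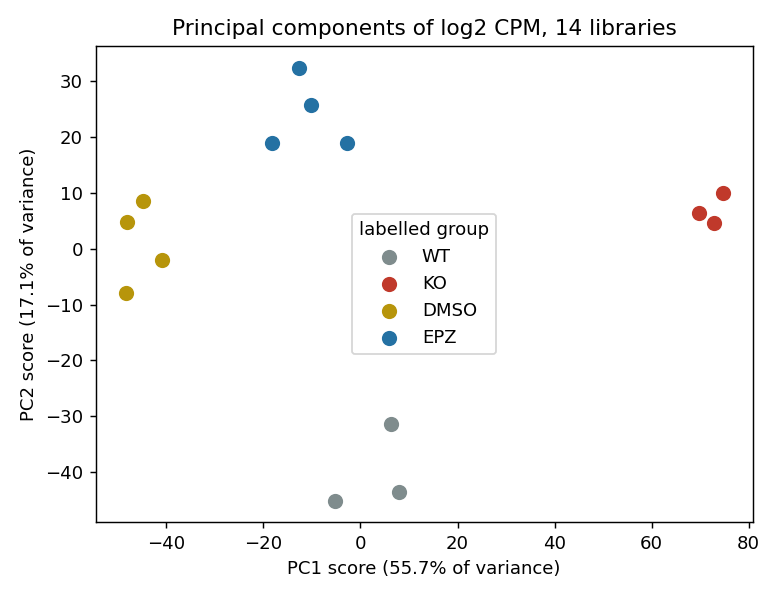
The 14 libraries by the first and second principal components of log2 CPM over 12639 genes, each axis with its percent of the variance, and each point a library coloured by group. The 3 KO libraries lie between 69.7 and 74.7 on the first component, and the 4 DMSO libraries between -48.4 and -40.9.

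The labels of the KO and WT libraries were checked against transcripts that report them. Dot1l (ENSMUSG00000061589, mm10 chromosome 10, 80755206 to 80795461, protein coding) was higher in all 3 KO-labelled libraries, at 203 ± 14.4 CPM against 136 ± 3.75 in WT (SD, n = 3 each), with a log2 fold change of 0.59 ± 0.07 (SE; adjusted p = 1.3e-05). Counts over the whole gene do not show whether part of it was deleted. The sex of 4 of the 6 KO and WT libraries, read from Xist on the X chromosome and Ddx3y on the Y, differed from its label, and that of all 8 DMSO and EPZ libraries matched. KO 2 and WT 3, labelled female, held Ddx3y at 125 and 139 CPM, and KO 3 and WT 2, labelled male, held Xist at 678 and 1650.2 CPM. Every direction given for KO below is that of the KO-labelled libraries over the WT-labelled ones. The higher Dot1l count does not bear out the KO label, and whole-gene counts cannot show that the label is wrong.

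The comparison of KO with WT asks what genetic loss of DOT1L does to the transcriptome of activated CD8 T cells. Prf1 and several granzyme genes were far higher in the KO-labelled libraries. Prf1, which encodes the pore-forming protein perforin (ENSMUSG00000037202, chromosome 10, 61297833 to 61304680), stood at 260 ± 37.8 CPM against 20.9 ± 6.83 in WT (SD, n = 3 each), a log2 fold change of 3.57 ± 0.16 (SE; adjusted p = 5.0e-09). Granzyme E (Gzme) rose from 1.76 ± 0.746 to 120 ± 28.7 CPM, by 5.91 ± 0.22 on the log2 scale. The transcripts of the CD8 co-receptor, which defines these cells, fell: Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173) from 706 ± 23.8 to 115 ± 23.2 CPM (log2 fold change -2.60 ± 0.11), and Cd8b1 from 574 ± 21.5 to 114 ± 9.08 CPM (-2.33 ± 0.07; adjusted p = 4.5e-10). Of 11570 genes tested with edgeR, 4678 were called, 2345 higher and 2333 lower in KO, and 802 and 255 of these changed at least 2-fold. At an unadjusted p under 0.05 the count was 5579, and against a minimum fold of 1.5 (glmTreat) 765 genes were higher and 305 lower.

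Among the genes with the largest rise were Gzmd (5.52 ± 0.25), Gzmg (6.06 ± 0.53), Scin (5.84 ± 0.20), Tns3 (5.93), Spns2 (5.77) and Col18a1 (6.16 ± 0.36, from 329 counts in KO and 4 in WT), all as log2 fold changes. For Emp2 and Alox5 the WT libraries together held 1 count, against 285 and 280 in KO, giving ratios of 265 (exact 95% interval 47.3 to 10522) and 261 (46.4 to 10338). The largest falls were taken under the naming rule, with at least 5 CPM, no overlap between the groups and no receptor segments. They were those of St6gal1, a sialyltransferase (2.45 ± 0.889 against 53.2 ± 12.8 CPM, log2 fold change -4.36 ± 0.22), Itgae, the integrin chain CD103 (-3.47 ± 0.21), Abca3 (-3.38), Fam71b (-3.29), Cd6, a surface receptor of T cells (28.1 ± 4.98 against 271 ± 23.8 CPM, -3.24 ± 0.11), Slc28a2b (-3.11), Ifngr2 (-2.99) and Cd8a.

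Of 20 cytotoxic effector molecules tested, 13 rose and 2 fell (camera adjusted p = 6.6e-06, and adjusted p = 0.332 with an estimated correlation; 15 called when adjusted over the list alone). Besides Prf1 and Gzme these included Gzmc (391 ± 91.8 against 32.5 ± 8.23 CPM). The granzymes C to G are close copies of each other in 1 cluster on chromosome 14, so the share of each is uncertain. Gzmb, the most abundant granzyme, changed far less, from 1815 ± 340 to 2304 ± 100.3 CPM (log2 fold change 0.35 ± 0.11, adjusted p = 0.018, and 0.0597 without KO 3), and Nkg7 stood at -0.08 (adjusted p = 0.382). Inhibitory receptors and exhaustion genes rose in 12 of 18 and fell in 3 (adjusted p = 0.0093, and 0.253 as an adjusted p with an estimated correlation; 15 adjusted over the list alone). Without KO 3 the adjusted p of this list was 0.0546. The nuclear receptor Nr4a3 rose by 1.94, while Btla (-2.53) and Vsir (-0.99) fell. Tox2 held 99 counts in KO and 3 in WT, a ratio of 30.7 (exact 95% interval 10.2 to 152). Pdcd1, encoding PD-1, was too weak to be tested, at 0.506 CPM in KO and 1.30 in WT. Heat shock and immediate early genes rose in 11 of 18 and fell in 2 (adjusted p = 0.00012, and adjusted p = 0.275 with an estimated correlation; 14 adjusted over the list alone), with Egr3 (3.14), Egr2 (2.39), Egr1 (1.62) and Hspd1 (0.57). Interferon response genes rose in 14 of 34 and fell in 3 (adjusted p = 0.0452, and adjusted p = 0.735 with an estimated correlation; 18 adjusted over the list alone), among them Ifi204 (4.36), Oasl1 (2.87) and Oasl2 (2.60). That call was lost without KO 3 (0.0569), without WT 2 (0.183), with the filter of 10 CPM (0.355) and with fry (0.0509).

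Naive and memory T cell genes fell in 19 of 24 and rose in 4 (adjusted p = 1.7e-07, and adjusted p = 0.113 with an estimated correlation; 23 adjusted over the list alone). Ccr7, the homing receptor of lymph nodes, fell from 79.6 to 14.0 CPM (log2 fold change -2.47 ± 0.08), and Satb1 (-1.51 ± 0.07) and Tcf7 (-0.76 ± 0.07) fell with it. Eomes rose by 0.30 ± 0.10 (adjusted p = 0.027), a call lost without KO 1 (0.103), KO 3 (0.0864), WT 2 (0.0819) or WT 3 (0.0613), and with all 14 libraries in 1 fit (0.0675). T cell receptor signalling genes fell in 22 of 32 and rose in 6 (adjusted p = 7.5e-06, and adjusted p = 0.113 with an estimated correlation; 30 adjusted over the list alone), with Cd8a, Cd8b1, Cd6 and Themis (-1.39 ± 0.06). Most genes tested from the marker lists of other lymphocytes fell as well. Whether their transcripts came from such cells or from the CD8 T cells was not tested. Il2ra and Ctla4 also stand in the lists of cytokine receptors and inhibitory receptors, and 3 of the 15 B cell markers were expressed enough to test. All 3 B cell markers tested fell, Ighm from 529 ± 53.1 to 124 ± 11.5 CPM, Ighd by 2.37 and Cd79b by 1.46 on the log2 scale (adjusted p = 0.0034, and adjusted p = 0.292 with an estimated correlation; 3 adjusted over the list alone). Of 6 CD4 and regulatory T cell markers 5 fell and 1 rose (adjusted p = 0.015, and adjusted p = 0.325 with an estimated correlation; 6 adjusted over the list alone), with Il2ra (-0.92) and Ctla4 (-0.91) down and Zbtb7b (0.70) up. The filter of 10 CPM ended this call (0.203). The 5 gamma delta T cell markers all fell, led by Trgc4 (-3.45) (adjusted p = 0.00028, and adjusted p = 0.268 with an estimated correlation; 5 adjusted over the list alone). Of the myeloid markers 2 were tested, H2-Ab1 (1.41) and Cd68 (-0.07, adjusted p = 0.793), too few for the list test, and 1 was called when adjusted over the list alone. Of the 12 erythroid and platelet markers 1 was tested, Itga2b (-0.80, adjusted p = 0.0586, and 0.0244 without KO 3), which passed when adjusted over the list alone.

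The other lists did not pass camera for KO against WT. Effector cytokines and chemokines rose in 4 of 13 and fell in 3 (adjusted p = 0.705; 9 adjusted over the list alone), with Ifng from 2.16 ± 0.871 to 12.2 ± 1.01 CPM (log2 fold change 2.47 ± 0.20, adjusted p = 7.6e-07), Xcl1 from 4.89 ± 1.03 to 71.2 ± 5.86 CPM, and Tnfsf8 (-1.46). NK receptors and adaptors rose in 9 of 20 and fell in 4 (0.055; 14), and passed without KO 1 (0.0369), without KO 2 (0.0492) and with replicate numbers as a block (0.0409). Klrk1 (-1.05) and Klrd1 (-0.51) fell, and those that rose included Fcer1g from 4.45 to 61.5 ± 12.8 CPM and Cd244a (2.54). Effector transcription factors rose in 6 of 18 and fell in 6 (0.921; 12), with Prdm1 (1.43), Zfp683 (-2.47) and Tbx21 (-0.46 ± 0.14, adjusted p = 0.017, but 0.0634 without KO 1, 0.0530 without WT 1 and 0.0597 with all 14 libraries in 1 fit). Type 2 and type 17 cytokine genes rose in 2 of 6 and fell in 3 (0.705; 5), cytokine and costimulatory receptors rose in 6 of 19 and fell in 8 (0.499; 14), and chemokine receptors and adhesion genes rose in 6 of 23 and fell in 8 (0.921; 15), with Itga1 up by 4.44. DOT1L and its partners rose in 1 of 10, Dot1l itself, and fell in 6 (0.129; 7), among them Aff1 (-0.69). MLL leukaemia DOT1L targets rose in 2 of 4 and fell in 2 (0.959; 4), with Zeb2 (1.86) and Jmjd1c (-0.91), and Polycomb and chromatin repressors rose in 4 of 25 and fell in 5 (0.834; 8). Cholesterol synthesis and uptake rose in 8 of 24 and fell in 3 (0.161; 12), with 0.0465 without WT 1. Glycolysis rose in 8 of 18 and fell in 5 (0.705; 13), and oxidative phosphorylation rose in 3 of 24 and fell in 1 (0.705; 0). Cell cycle genes rose in 4 of 35 and fell in 5 (0.752; 8), p53 targets and apoptosis genes rose in 7 of 21 and fell in 7 (0.613; 14), and the integrated stress response rose in 6 of 14 and fell in 3 (0.331; 9). With fry, which tests a list by itself and not against other genes, the NK (0.0062), cytokine receptor (0.0051) and DOT1L partner (0.0493) lists passed. In the pairs of numbers the first is the adjusted p of camera and the second the members called when adjusted over the list alone. Median and mean log2 fold change of the MLL list were 0.56 and 0.53 while camera ranked it down, those of the chemokine receptors -0.07 and 0.18 with camera down, those of the p53 targets -0.09 and 0.0039 with camera down, those of the effector transcription factors -0.02 and 0.03 with camera up, and those of the Polycomb list 0.0033 and -0.016 with camera down.

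**Figure D2:**
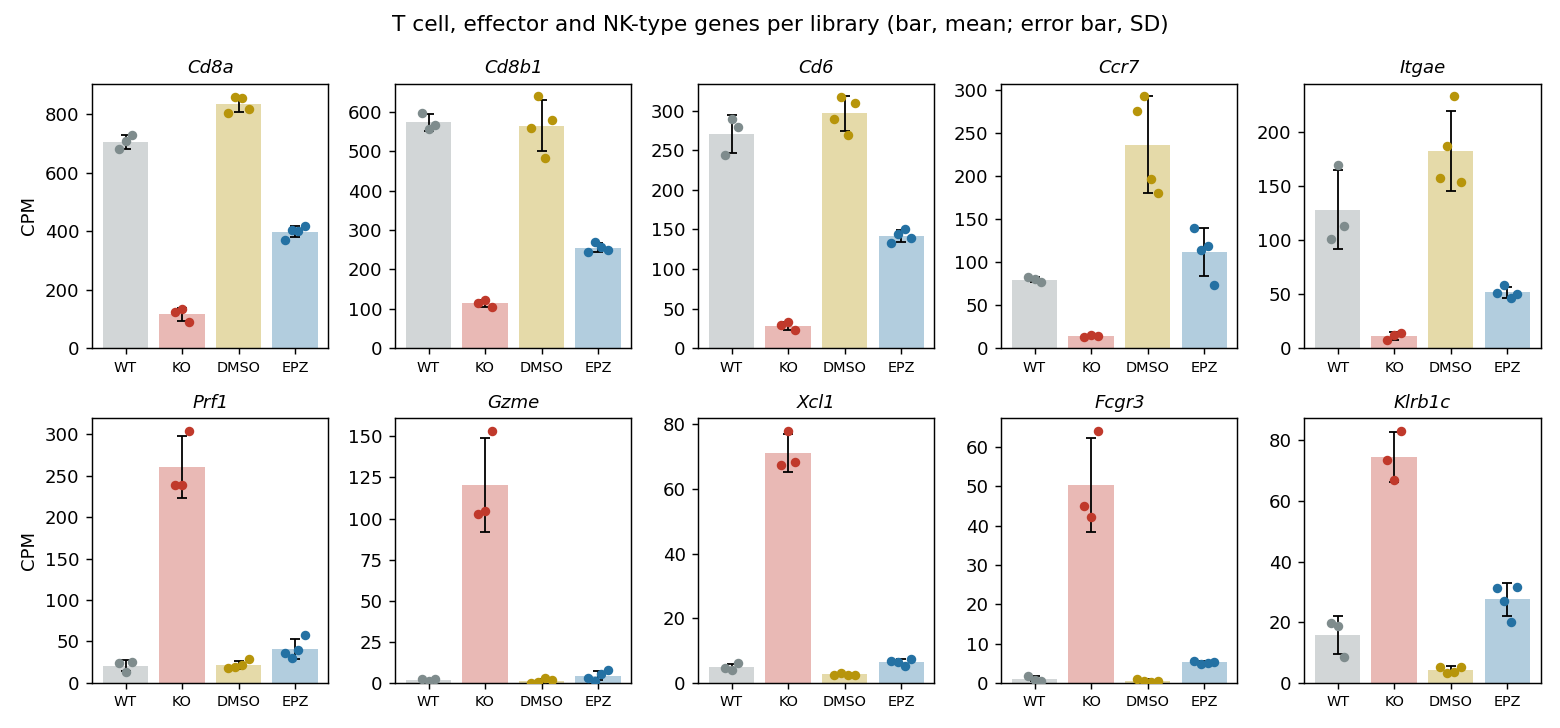
Normalised read counts in CPM of 10 genes in each library, with points for libraries, bars for the group mean and error bars for 1 SD (n = 3 for KO and WT, 4 for DMSO and EPZ). Cd8a stood at 706 CPM in WT and 115 in KO, and at 834 in DMSO and 399 in EPZ.

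The comparison of EPZ with DMSO asks what catalytic inhibition of DOT1L does in wild-type CD8 T cells from mice without Cre or floxed alleles. The CD8 co-receptor fell here too, Cd8a from 834 ± 27.1 to 399 ± 20.2 CPM (SD, n = 4 each; log2 fold change -1.06 ± 0.06 SE, adjusted p = 8.5e-06) and Cd8b1 from 566 ± 64.8 to 255 ± 11.6 CPM (-1.15 ± 0.08). Some receptor genes of NK cells rose, although their list did not pass as a group (adjusted p = 0.0931) and Klrd1 fell by 0.38 on the log2 scale. Klrb1c, encoding NK1.1, reached 27.5 ± 5.42 CPM from a mean of 4.38 (2.62 ± 0.19, adjusted p = 1.1e-05), and Fcgr3, encoding the Fc receptor CD16, rose from 0.555 ± 0.349 to 5.21 ± 0.263 CPM (3.02 ± 0.27). Prf1 rose from 21.8 ± 4.86 to 40.8 ± 11.7 CPM (0.91 ± 0.20, adjusted p = 0.0079). Dot1l was measured at 101 ± 10.8 CPM in EPZ and 90.5 ± 6.81 in DMSO (0.16 ± 0.08, adjusted p = 0.217). Of 12208 genes tested with edgeR, 2463 were called, 1449 higher and 1014 lower, and 431 and 69 of these changed at least 2-fold. At an unadjusted p under 0.05 the count was 4173. With the animal as a block, 1792 genes were higher and 1371 lower. The 1449 became 879 with the filter of 10 CPM and 957 with thinned counts, the 1014 became 610 without EPZ 4, and glmTreat gave 237 and 37.

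The largest rises also took in Wfikkn2 (2.80), Ppp2r2c (2.73), Tgm2 (2.66), Kifc3 (2.58), the tyrosine kinase gene Syk (2.29) and the transcription factor gene Maf (2.28 ± 0.16), as log2 fold changes. Among the largest falls were Slc28a2b (-1.95 ± 0.15), Morc1 (-1.94), Itgae (from 183 ± 36.9 to 51.6 ± 5.28 CPM, -1.82 ± 0.13), Ncf1 (-1.54), Prkch, a protein kinase C gene (from 320 ± 15.8 to 116 ± 12.5 CPM, -1.46 ± 0.08), Fam71b (-1.40), BE692007 (-1.38) and Zfp683 (-1.37). Among the genes fixed by name, Ifng rose from 0.723 ± 0.337 to 2.31 ± 0.631 CPM (1.77 ± 0.32), Eomes rose by 0.65 ± 0.09 and Tcf7 fell by 0.60 ± 0.12. The values for Gzmb (-0.06 ± 0.09, adjusted p = 0.679), Tbx21 (-0.07, adjusted p = 0.774) and Pdcd1 (-0.01 ± 0.28, adjusted p = 0.981) did not pass.

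Cytotoxic effector molecules rose in 9 of 19 and fell in 0 (camera adjusted p = 0.00019, and adjusted p = 0.271 with an estimated correlation; 14 adjusted over the list alone), with Gzma from 87.0 to 177 CPM, Serpinb9b (2.17), Serpinb9 (0.83) and Fasl (0.47). Cell cycle genes rose in 13 of 35 and fell in 0 (adjusted p = 2.4e-06, and adjusted p = 0.466 with an estimated correlation; 16 adjusted over the list alone), with Mcm2 (from 123 to 193 CPM, 0.65 ± 0.11), Ccne2 (0.54), Mcm6 (0.40) and Pcna (0.37). Cholesterol synthesis and uptake rose in 11 of 24 and fell in 0 (adjusted p = 0.00052, and adjusted p = 0.468 with an estimated correlation; 17 adjusted over the list alone), with Idi1 (0.52), Hmgcs1 (0.47) and Msmo1 (0.35). With fry, the calls of the cell cycle and cholesterol lists were lost (adjusted p = 0.0813 each). Glycolysis rose in 10 of 18 and fell in 1 (adjusted p = 0.00052, and adjusted p = 0.437 with an estimated correlation; 13 adjusted over the list alone), with Tpi1 (0.74), Ldha (0.38) and Pgk1 (0.29) up and Pdk1 (-0.40) down. Interferon response genes rose in 9 of 34 and fell in 1 (adjusted p = 0.0072, and adjusted p = 0.309 with an estimated correlation; 11 adjusted over the list alone), with Ifi204 (2.09), Oasl2 (1.33), Gbp2 (0.31) and Ifi203 (-0.28).

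Naive and memory T cell genes fell in 11 of 25 and rose in 3 (adjusted p = 0.00033, and adjusted p = 0.309 with an estimated correlation; 19 adjusted over the list alone), with Myb (-0.87), Il6st (-0.83) and Lef1 (-0.63) down. T cell receptor signalling genes fell in 10 of 32 and rose in 2 (adjusted p = 2.1e-05, and adjusted p = 0.309 with an estimated correlation; 20 adjusted over the list alone), with Cd8a, Cd8b1, Cd6 (from 297 to 142 CPM) and Cd5 (-0.66). Of 3 B cell markers 2 fell, Ighm from 1105 ± 116 to 489 ± 61.4 CPM and Ighd by 1.54 on the log2 scale, and Cd79b stood at -0.07 (adjusted p = 0.754); the list had adjusted p = 0.0027, and adjusted p = 0.271 with an estimated correlation, and 2 members adjusted over the list alone. Without EPZ 3 that list had adjusted p = 0.0785. Of 7 CD4 and regulatory T cell markers 4 fell, with Cd4 from 3.36 to 1.36 CPM and Foxp3 from 12.6 to 5.29 CPM (adjusted p = 0.0048, and adjusted p = 0.271 with an estimated correlation; 5 adjusted over the list alone). The filter of 10 CPM ended this call (0.0885).

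The remaining lists did not pass camera for EPZ against DMSO, and the numbers given are again its adjusted p and the members adjusted over the list alone. NK receptors and adaptors rose in 6 of 18 and fell in 2 (0.0931; 10), with Klrb1c and Fcgr3 among the largest changes. Type 2 and type 17 cytokine genes rose in 4 of 7 and fell in 1 (0.0931; 5), with Maf and Ccr8 (1.85). Without EPZ 2, the NK list (0.0263), this list (0.0458) and DOT1L and its partners (0.0411) passed. Effector cytokines and chemokines rose in 4 of 13 and fell in 3 (0.531; 8), with Xcl1 (1.28) and Ltb (-0.71), and effector transcription factors rose in 5 of 18 and fell in 4 (0.535; 13), with Id2 (0.84 ± 0.07). Inhibitory receptors and exhaustion genes rose in 3 of 20 and fell in 4 (0.699; 7), with Ctla4 (-1.27) and Btla (-0.84). The median of that list was 0.02 and its mean -0.02. Cytokine and costimulatory receptors rose in 3 of 19 and fell in 3 (0.535; 6), and chemokine receptors and adhesion genes rose in 7 of 23 and fell in 5 (0.305; 14), with Cx3cr1 (1.44). DOT1L and its partners rose in 0 of 10 and fell in 2, Aff1 (-0.50) and Aff3 (-0.48) (0.085; 2). MLL leukaemia DOT1L targets rose in 1 of 4, Zeb2 (1.07), and fell in 0 (0.316; 3), with Jmjd1c at -0.42 ± 0.14 (adjusted p = 0.0531). Jmjd1c passed with the animal as a block (0.0432), without DMSO 1 (0.0119) and without EPZ 2 (0.0337). It also passed with RLE (0.0448), no filter (0.0055), DESeq2 (0.0145) and all 14 libraries in 1 fit (0.0202). Polycomb and chromatin repressors rose in 5 of 25 and fell in 2 (0.198; 7), with Tet1 (1.18). Oxidative phosphorylation rose in 2 of 24 and fell in 0 (0.102; 1), and passed with the filter of 10 CPM (0.0455). The p53 targets and apoptosis genes rose in 0 of 20 and fell in 7 (0.188; 9), and heat shock and immediate early genes rose in 5 of 18 and fell in 1 (0.129; 11). The integrated stress response rose in 4 of 15 and fell in 2 (0.0896; 6), and passed with the animal as a block (adjusted p = 0.0262). Without DMSO 4 this list and the heat shock list each had adjusted p = 0.0390. Gamma delta T cell markers rose in 0 of 5 and fell in 1, Trgc4 (-0.89) (0.268; 1), with Trgc2 at -0.37 ± 0.14 (adjusted p = 0.0911, and 0.0119 with the animal as a block, 0.0383 without EPZ 3 and 0.0482 with no filter). With fry, the NK (0.0060), type 2 and type 17 (0.0027), chemokine receptor (0.0040), DOT1L partner (0.0119) and Polycomb (0.0262) lists passed. Of the myeloid markers tested, H2-Ab1 stood at 1.78 and Cd68 at -0.17, with 1 called when adjusted over the list alone. The only erythroid and platelet marker tested, Itga2b, stood at -0.27 (adjusted p = 0.504), with 0 called.

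**Figure D3:**
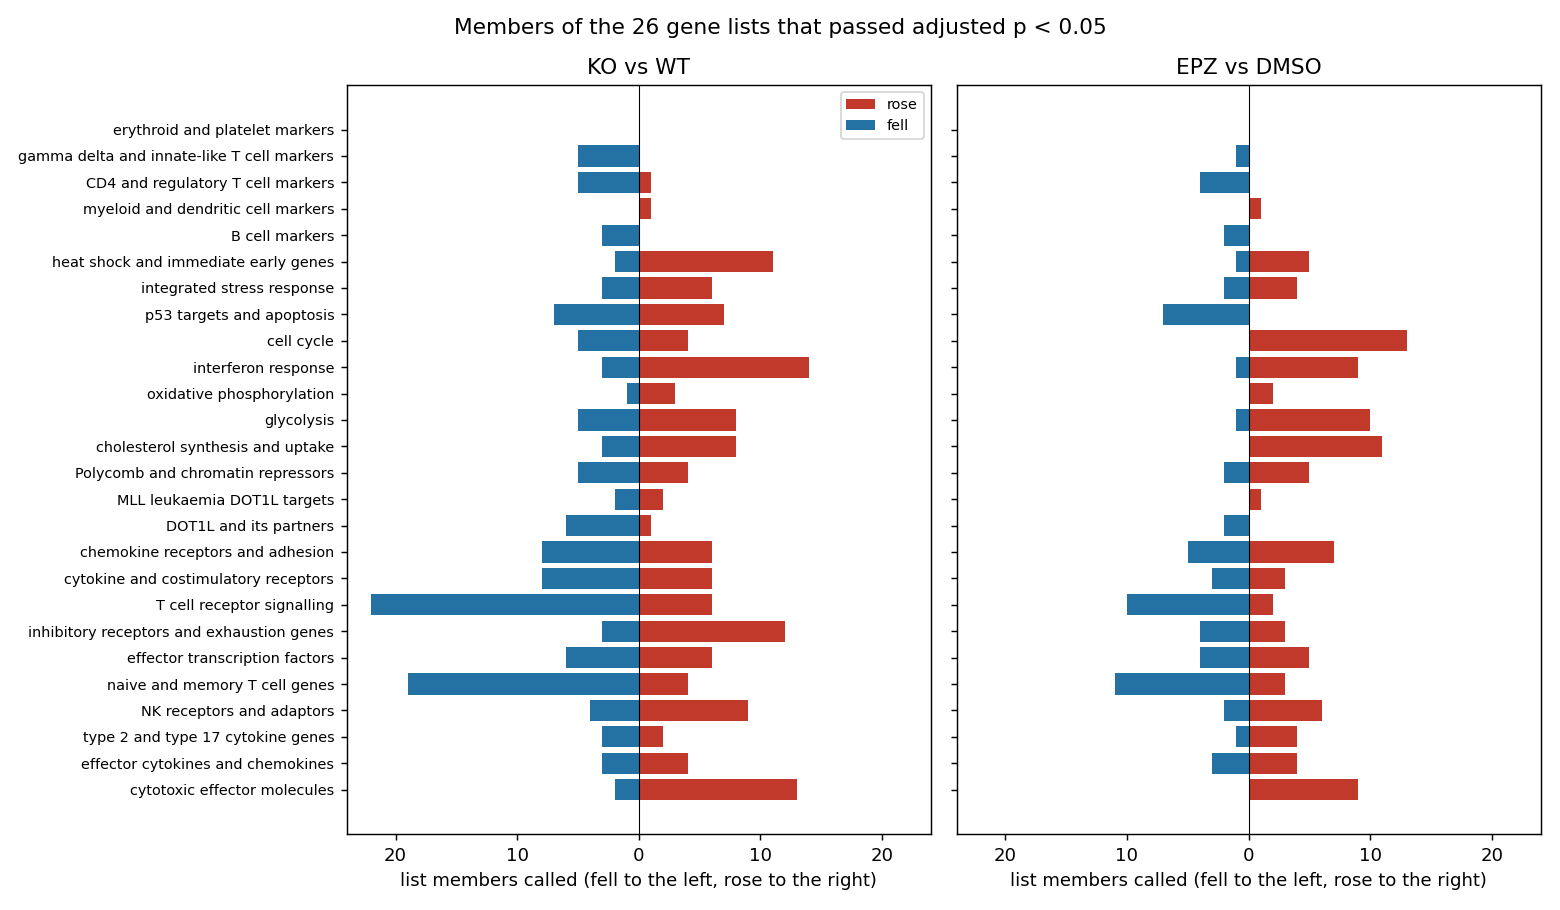
The number of members of each of the 26 lists that rose or fell at an adjusted p under 0.05 in KO against WT and in EPZ against DMSO. T cell receptor signalling had 22 members that fell in KO and 10 in EPZ, and cell cycle genes had 13 that rose in EPZ and 4 in KO.

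The question shared by both experiments is whether loss and inhibition of DOT1L move the same genes. Whole-gene counts of Dot1l neither bear out nor refute the KO label, so a direction in KO is that of the KO-labelled libraries. Among the genes called in both, Fcgr3 rose by 5.77 in KO and 3.02 in EPZ on the log2 scale, Syk by 4.11 and 2.29, Kifc3 by 3.59 and 2.58, Ppp2r2c by 4.06 and 2.73, and Klrb1c by 2.39 and 2.62. Marcks (3.08 and 2.26), Itgb5 (2.32 in KO) and Trf (4.88 and 2.07) rose in both as well. Of 11364 genes tested in both comparisons, 982 were higher in both where 267 would be by chance, and 703 were lower in both where 198 would be (Fisher's exact test across genes, p = 2.2e-302 for the lower genes). The comparisons share no control library. Log2 fold changes correlated across genes with Pearson r = 0.789 (0.387 with no filter) and Spearman rho = 0.632, and genes are not independent replicates. With the animal as a block in EPZ alone, 1991 genes were called in both in the same direction, against 1685 without it, and glmTreat gave 224.

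**Figure D4:**
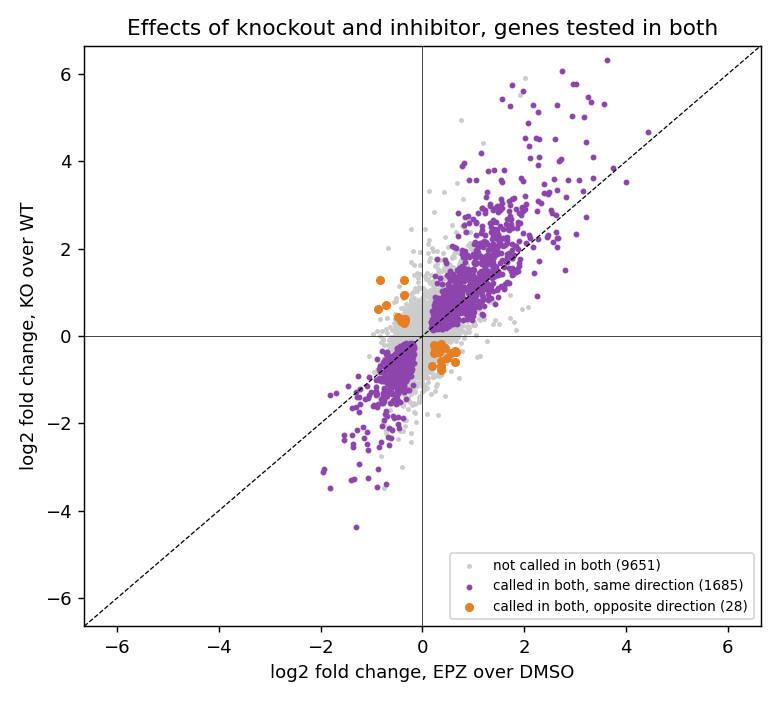
Log2 fold change in KO against WT and in EPZ against DMSO for the 11364 genes tested in both, each point a gene coloured by whether it was called in both. In all, 1685 genes were called in both in the same direction and 28 in opposite directions.

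The contrast of the effects asks which genes respond to the KO label more or less than to the inhibitor. Spp1, encoding the secreted protein osteopontin, rose more in KO by 4.00 ± 0.47 on the log2 scale (SE; edgeR adjusted p = 6.1e-05), from 6.53 ± 2.48 CPM in WT to 376 ± 82.3 in KO. Adamts14 (4.20 ± 0.84), Npnt (4.22 ± 1.09) and Scin (4.11 ± 1.02) also rose more in KO. Cd6 fell more in KO, by a difference of -2.19 ± 0.14 (adjusted p = 3.8e-07), as did St6gal1 (-3.08 ± 0.38), Abca3 (-2.69 ± 0.24), Ifngr2 (-2.60 ± 0.31) and Acvrl1 (-2.22 ± 0.25). Of 12639 genes tested, 961 were called, 416 with a higher effect in KO and 545 with a lower one, and 2796 had an unadjusted p under 0.05. Which side holds more depends on the scaling, with 486 higher and 461 lower with RLE, and 544 and 531 with DESeq2. Emp2 had a difference of 5.78 ± 1.60 (adjusted p = 0.0362), which did not pass with replicate numbers as a block (0.0543). It also did not pass without KO 2 (0.0543), KO 3 (0.0585), WT 1 (0.0635), WT 2 (0.0623), WT 3 (0.0625), DMSO 1 (0.0881), DMSO 3 (0.224) or EPZ 2 (0.0508), or with thinned counts (0.198). Npnt did not pass without KO 3 (0.0532), WT 1 (0.0542), WT 3 (0.0787), DMSO 2 (0.0748), DMSO 3 (0.0569) or DMSO 4 (0.0586), or with limma voom (0.0811), nor did Scin without DMSO 1 (0.108) or DMSO 3 (0.0702). The contrast called 7.60% of all genes tested. It called 17 of 32 listed T cell receptor signalling genes, 10 of 25 naive and memory genes, 8 of 21 inhibitory receptors and exhaustion genes, and 7 of 20 cytotoxic effector molecules. Lists with 0 called included the cell cycle (35 listed), cholesterol synthesis and uptake (25), oxidative phosphorylation (24) and the integrated stress response (18). A count of 0 does not show equal effects, since 56.1% of simulated 1.5-fold changes were recovered in the contrast. Of 931 genes called by the contrast and tested in both comparisons, 585 had fitted changes of the same sign that were larger in KO, 16 of the same sign that were larger in EPZ, and 330 of opposite sign. Of these, 28 were called in both comparisons in opposite directions. Leaving out KO 3 lowered the 961 calls to 627. Experiment, mouse line, 4-hydroxytamoxifen and inhibitor dose differ between the comparisons together with the perturbation. The control groups differed as well. On the first principal component WT lay from -5.22 to 7.92 and DMSO from -48.4 to -40.9, so the 2 effects start from different baselines.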

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

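The tests on Dot1l and the sex entries, on cell types and granzymes, and on the selection of genes by their KO effect were chosen after the result was seen.

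Dot1l was higher in the KO-labelled libraries, at 218, 201 and 190 CPM against 135, 140 and 133 in WT, and 4 of their 6 sex entries did not match Xist and Ddx3y. An exchange of 1 or 2 library pairs between the groups is argued against, since 0 of 6 libraries lay nearer to the other group, with distances of 0.158 to 0.270 to the own group and 0.555 to 0.629 to the other. An exchange of all 6 labels is not settled by the sex entries, of which 6 of 6 match after it. However, 6 of 6 also match if the numbers 2 and 3 are exchanged within both groups, which changes no group comparison. With all labels exchanged, the correlation with EPZ effects would turn to -0.789. The 1685 of 1713 genes called in both that moved the same way would then move in opposite ways. This argues against the exchange only if loss and inhibition of DOT1L act alike, so it stays open. A response of the transcript to lost DOT1L activity may also have raised Dot1l, and its rise was 0.43 ± 0.12 (SE, log2) larger than under EPZ (edgeR adjusted p = 0.0332, from 0.0126 to 0.0999 with 1 library left out, and not called in 5 of 14 such fits). A deletion that leaves most of the transcript in place was not tested, and the directions given for KO rest on the labels.

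In the KO-labelled libraries, CD8 and T cell receptor signalling genes fell, while granzyme genes and some NK receptor genes rose. Replacement of T cells by other cells is argued against as the whole cause by Cd3d, Cd3e and Cd3g, whose median log2 fold change was -0.00051, although Cd3d (-0.71), Cd247 (-0.43), Trac (-1.45), Cd5 (-2.10) and Bcl11b (-2.11) fell. Whether NK cells or macrophages were added is not decided. Klra4, Klra7, Klra8 and Lyz2 had a highest mean of 0.135 CPM in KO. Genes this near the floor cannot decide it, since the level that added cells would bring is not known. Among other NK genes, Ncr1 (4.52 CPM in KO, 0 counts in WT) and Tyrobp (9.66 against 0.690 CPM) rose, while Klrk1 (-1.05) and Klrd1 (-0.51) fell. Reads shared between granzyme copies do not account for the rise of the granzyme genes. The sum of Gzmc to Gzmg was 19.3-fold higher, at 746 ± 190 against 38.6 ± 10.3 CPM (SD, n = 3 each). A changed state of the CD8 T cells, another mixture of T cell subsets, or a few basophils or mast cells, whose genes Mcpt8 (10.5 against 0.167 CPM) and Cpa3 (6.11 against 0.566 CPM) rose, may each contribute and were not tested.

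Effects were larger in KO against WT than in EPZ against DMSO, with SDs of log2 fold changes, less their error, of 0.445 and 0.256 over 8597 genes. A difference in depth or spread is argued against, since the ratio of these SDs was 1.74, 1.73 with counts thinned to 1 depth, and 1.66 to 1.89 with 1 library left out. Whether selection of genes by their KO effect adds to this is not settled by the same ratio of 1.74. Its genes were chosen by a mean of at least 10 CPM over all 14 libraries, KO included. A gene such as Car2 (66.4 CPM in KO, 1.31 in WT, 2.12 in DMSO and 8.11 in EPZ) enters through its KO level. Of the genes called under EPZ, 54.3% had the larger effect in KO. Stronger loss of DOT1L activity in KO, a partial dose of inhibitor, the mouse line and 4-hydroxytamoxifen may each contribute and cannot be told apart, because they differ between the experiments together.

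A split of the libraries other than the real one gave at most 0 genes for KO against WT, where the real split gave 4678 and 1 of 10 splits gave as many, which are too few splits for a share under 0.05. For EPZ against DMSO, 1 of 35 splits, the real one, gave 2463 genes and the highest other gave 5. Among the 8 splits that part all 4 animals, too few for a share under 0.05, the highest other gave 0. For the contrast of the effects, 9 of 100 splits drawn from 350 gave at least the real 961, and the highest other gave 1695. This decides nothing, since all 8 others as large keep the real split of KO and WT and so its effect, and the 83 that keep neither real split gave at most 0. For genes called in both, 1 of 350 splits gave the real 1685 and the highest other gave 0, which decides nothing, since the other splits of KO and WT called 0 genes and so fixed the overlap at 0. For the lists, KO against WT gave 9, the highest other split 10 and the median other 2. As many were called in 2 of 10 splits, which are too few for a share under 0.05, so another grouping did as well. EPZ against DMSO gave 9 lists, the highest other 10 and the median other 5. As many were called in 5 of 35 splits, a share not under 0.05. The number of lists called thus does not set the real grouping apart in either comparison. Among the 8 splits that part all 4 animals, too few for a share under 0.05, the highest other gave 9.

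Single libraries stood apart from the other 3 of their group in 10 of 184 groups tested, where chance gives about 9.2 at 1 in 20. In DMSO 2, Dot1l stood at 80.4 CPM (others 92.3 to 94.7) and Pdk1 at 318 (257 to 262). In DMSO 3, Ifng stood at 1.23 CPM (0.516 to 0.575) and Cd79b at 7.97 (9.81 to 10.2). In EPZ 2, Slc28a2b stood at 10.9 CPM (13.1 to 13.3). In EPZ 3, Msmo1 stood at 46.9 CPM (55.2 to 55.9) and Psat1 at 139 (172 to 177). In EPZ 4, Tgm2 stood at 16.9 CPM (11.6 to 11.9), Cycs at 44.9 (38.8 to 39.8) and Trp53inp1 at 407 (492 to 503).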

How the results depend on the processing

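The covariate for the sex read from transcripts and the thinned counts were alternatives and tests chosen after the data were seen. No named gene or list that passed, in the reported fit or under an alternative run, changed direction between them, while the balance of higher and lower genes did turn in the contrast (416 and 545, against 486 and 461 with RLE). With a minimum fold of 1.5 (glmTreat), a stricter question by construction, 765 genes were higher and 305 lower in KO (2345 and 2333 without it), 237 higher and 37 lower in EPZ (1449 and 1014), and 224 shared (1685). The filter of 10 CPM left 8669 genes to test and 879 higher in EPZ, and counts thinned to the smallest library gave 957. With an estimated correlation 0 lists passed in KO and 0 in EPZ, against 9 and 9, with smallest adjusted p of 0.113 and 0.271. The correlation of the effects, 0.789, was 0.387 with no filter and 0.722 with thinned counts, and the cause was not tested. With 1 library left out, the genes lower in EPZ numbered 610 (without EPZ 4) to 1060 (without EPZ 3), and those called by the contrast 627 (without KO 3) to 1059 (without DMSO 3). The other ranges were 1877 to 2280 higher and 1628 to 2299 lower in KO, 979 to 1327 higher in EPZ, 1240 to 1651 shared, and 7 to 10 lists in KO and 8 to 12 in EPZ. With RLE, voom and DESeq2, the genes higher in KO numbered 2392, 2369 and 1995. Of 1561 values of the genes named in KO under alternatives 1521 kept their call, as did 1565 of 1633 in EPZ and 201 of 220 in the contrast. Of the list values, 240 of 262 in KO and 284 of 309 in EPZ did. Most named genes were chosen for their large or clear changes in these same data, so their shares do not speak for all calls. With thinned counts, 79.8% of all genes called in KO, 63.8% in EPZ and 62.6% in the contrast stayed called. Without DMSO 2, 64.0% of those in EPZ did. In simulated data with the depth and number of these libraries and a common spread for all genes, 82.8% of 1.5-fold changes were recovered in KO, 84.4% in EPZ and 56.1% in the contrast.

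With the replicate block, KO against WT gave 2128 genes higher and 2138 lower, EPZ against DMSO 1792 and 1371, the contrast 1102, and both fits 1904 shared genes, with 10 lists in each comparison. In KO and WT the numbers do not pair the libraries (correlations -0.172 to 0.0405, with 0 of 3 closest to its own number).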

Other observations

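The genes in the first paragraph, the tests of the EPZ effect by sex, and the genes that changed in opposite directions, were chosen after their values were seen, while the tests on expression level and on neighbouring genes were chosen before.

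Some genes outside the fixed lists were higher in the KO-labelled libraries, and some of them under EPZ too. Kit, the receptor of stem cell factor, rose from 16.8 to 104 CPM in KO (log2 fold change 2.69 ± 0.13 SE, n = 3 each) and from 17.9 to 55.2 CPM in EPZ (1.66 ± 0.16, n = 4 each). Lyn (2.43 in KO and 1.17 in EPZ), Lat2 (2.05 and 0.62), Spp1 (5.74 and 1.75) and Car2 (5.61 and 1.99) rose in both. Tyrobp stood at 9.66 CPM in KO and 0.690 in WT, and its log2 fold change in EPZ was 0.68 (adjusted p = 0.210). Ncr1, encoding the NK receptor NKp46, held 164 counts in KO and 0 in WT, at least 51.9-fold higher over a floor of 3 counts over the group. Bcl11b, a transcription factor of T cell identity, fell by 2.11 ± 0.10 in KO, from 126 to 28.9 CPM, and by 0.46 in EPZ. The T cell receptor chain Trac fell by 1.45 and 0.33 on the log2 scale, while Cd3e stood at 0.16 and Cd3g at -0.00051 in KO.

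In 28 genes called in both comparisons the direction was opposite. The contrast of the effects called all 28, which is no separate support. It used the same libraries, and opposite effects add up in it. The count of genes called in opposite directions was 17 without DMSO 2 and 17 without EPZ 4. It was 43 with the replicate block in both fits, 52 with the animal as a block in the EPZ fit alone, and 0 with glmTreat. Tox, a transcription factor of T cell exhaustion, rose by 1.28 in KO and fell by 0.35 in EPZ, and Myb rose by 0.62 and fell by 0.87. The glycolytic gene Hk2 fell by 0.36 in KO and rose by 0.66 in EPZ. The EPZ effect was called different between female and male animals for 0 of 12208 genes (edgeR, 334 at an unadjusted p under 0.05, 2 animals per sex and group), and with the animal as a block for 0 as well (484 at an unadjusted p under 0.05).

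Weakly expressed genes were tested for a rise and strongly expressed genes for a fall. Among KO genes called and changed at least 2-fold, 81.6% of 792 in the lowest expression band and 42.0% of 100 in the highest were higher, 39.6 percentage points apart. In EPZ the shares were 88.9% of 450 and 29.4% of 17, 59.5 points apart, and the exact 95% intervals of the shares (85.6 to 91.6% and 10.3 to 56.0%) did not overlap. Genes are not independent, and 17 are few. Over all genes called in EPZ, 80.2% of 858 and 41.7% of 905 were higher. Neighbouring called genes, at most 100 kb apart, were tested for a shared direction against 10000 shuffles of the directions. In KO, 60.3% of 2292 pairs moved the same way, where shuffles gave 48.0 to 52.0%, and in EPZ 63.9% of 740 pairs did, where shuffles gave 47.8 to 55.1% (permutation p = 0.0002 each, two-sided, the smallest the shuffles can give). Pairs at least 10 kb apart gave 57.5% of 1487 in KO and 62.1% of 523 in EPZ. The shuffles did not account for expression level, and a shared regional response was not tested as the cause.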
